A study of Drosophila melanogaster with 2 samples.

How the data were processed

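The data are signals from 2 Affymetrix expression arrays of Drosophila melanogaster embryos, 1 of a yw stock and 1 of embryos homozygous for a mutation in tdf. The gene tdf is now called apontic (apt) and encodes a DNA-binding transcription factor. Per the labels, embryos were kept until 16 h after egg laying at 25 °C on apple juice plates, tdf homozygotes were picked with a GFP-marked CyO balancer chromosome, and total RNA of each genotype was extracted separately and labelled with biotin by in vitro transcription. The yw stock takes its name from the body colour gene yellow (y) and the eye colour gene white (w). The allele of tdf, the length of the egg collection and the number of embryos per extract are not given in the sources used here.

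The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with MAS5 (Affymetrix Microarray Suite), per the submitters' processing notes. The MAS5 version, target signal and other settings are not given in the sources used here. After the lowest and highest 2% of probe sets were left out, the mean signal was 500.1 on both arrays, so each array had been scaled as a whole. MAS5 subtracts an estimate of mismatch hybridisation, which leaves dim probe sets noisy, and a single scaling factor cannot correct a trend of the ratio with brightness. Detection calls were not used here.

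Probe sets were named through the platform annotation. Of 14010 probe sets, 44 were controls and 13966 were gene probe sets, of which 12442 named 1 gene, 327 named several and 1197 named none. For 12393 probe sets the symbol was updated by gene ID to that of the RefSeq gene table of the assembly Release 6 plus ISO1 MT. No gene was named from a probe set that names several. A gene was represented by its probe set of highest mean signal, which gave 10843 genes, 1209 of them with 2 or more probe sets. The array values name no genome build, so no coordinates are given. The planned count by chromosome arm and by distance from apt was replaced by a count over the 50 and the 250 genes on each side of apt in the gene order of that assembly.

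Each genotype has 1 array. The difference between the arrays therefore has no replicate check, and no test, standard error or p-value was computed. The floor was the 40th percentile of the gene probe sets over both arrays, a signal of 97.3. Signals below it were raised to it before the log2 ratio (tdf over yw) was taken, so a ratio with 1 side below the floor is a lower bound, written as "at least". A gene was called measured when its higher signal was at or above the floor. Genes at least 2-fold apart were counted in each direction as a fixed rule of size. The spread within the arrays was described by the SD of the log2 ratio between probe sets of the same gene and by the spiked-in controls, which measure the arrays and not biological variation.

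There were 31 gene lists, covering pathways, tissues, cell types and control processes. For each of the 29 lists with at least 5 measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. That percentile describes these arrays and is not a p-value. The lists, the floor, the fold rule, the alternatives and the rule for named genes were fixed before the data were examined. The exception is that the patterns for cytochrome P450 genes and for lysozymes were narrowed afterwards, because they had taken in the cyclophilin Cyp1 and the lysyl-tRNA synthetase LysRS. The genes named are apt, y and w, the 8 genes with the highest and the 8 with the lowest ratio, the next 6 on each side whose symbol is not a CG or CR number, and in each list the up to 4 members with the largest ratio in size plus the brightest member. Any other gene named was chosen after its values were seen.

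The steps were tested on simulated arrays with 7428 measured genes, 50 of them changed at each of 4 fold sizes. The log2 ratio SD was 0.533, the same for dim and bright probe sets. The 2-fold rule took 42% of genes simulated at 2-fold, 76% at 2.83-fold, 86% at 4-fold and 98% at 8-fold. Of 7205 unchanged genes, 193 came out at least 2-fold higher and 194 at least 2-fold lower, and 1 was at least 4-fold apart. A simulated list of 27 genes shifted by -0.6 had a median log2 ratio of -0.65.

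The alternatives were centring of the log2 ratios on their median, quantile normalisation, loess of the ratio on mean signal (span 0.3), floors at the 25th and 60th percentile, the mean over all probe sets of a gene, plain probe sets only (those whose name has no suffix letter), limits of 1.5-fold and 3-fold, and a limit of 3 local median absolute deviations over 500 genes of similar signal. Added after the data were examined were list medians over members above the floor on both arrays, the germ line list without CycB, and counts over genes with a mean signal of at least 500. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.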

Results

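Gene expression was measured in late Drosophila embryos on 1 array of yw embryos and 1 array of homozygous tdf mutant embryos, to find genes whose expression depends on the transcription factor TDF, also called Apontic. There are no replicates, so each value below is a single measurement. Because yw is a separate stock, other differences between the stocks cannot be told apart from an effect of tdf. The median signal over the 14010 probe sets was 153 on the yw array and 154 on the array labelled tdf, and 59.2% and 60.8% of gene probe sets were at or above the floor of 97.3. Of 10843 genes, 7639 were measured, 6508 of them above the floor on both arrays. Across those 6508 genes, which are not independent replicates, the log2 signals of the arrays had a Pearson r of 0.936. Higher and lower refer throughout to the array labelled tdf relative to the yw array.

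The signal of apt itself was 979 on the yw array and 1051 on the array labelled tdf, a log2 ratio of 0.10. The apt signal was thus not lower on the array labelled tdf. Whether this probe set lies within the lesion is not given in the sources used here, so it does not check the label, and the wording "array labelled tdf" is kept for that reason. The body colour gene y, a marker of the yw stock, had signals of 563 and 628, and w was not named by any probe set.

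The genes with the lowest ratios included several regulators of mitosis. The mitotic cyclin CycB had a signal of 9664 on the yw array and 928 on the array labelled tdf, 10.4-fold lower, and CycB3 had 3423 and 378, 9.04-fold lower. The Cdc25 phosphatase twe was at least 8.86-fold lower (862 against 69.7). The anaphase activator fzy was 6.72-fold lower, and the mitotic kinase gwl at least 6.61-fold lower. Smaug (smg), an RNA-binding protein that directs the destruction of maternal mRNA, had 1528 against 73.5, at least 15.7-fold lower. The bicoid mRNA localisation factor swa was at least 11.4-fold lower (1109 against 87.9), and its second probe set was below the floor on both arrays. Of 2 genes that act when the blastoderm becomes cellular, dah was 10.9-fold lower (1623 against 148) and kuk 8.24-fold lower (2435 against 295). The histone chaperone Nasp was at least 13.7-fold lower, the polarity gene par-6 at least 7.74-fold lower and CG4880, at 1548 against 84.9, at least 15.9-fold lower. Jon99Fi, a serine protease gene, was 6.98-fold lower, and Naxd, an enzyme that repairs hydrated NADH, 6.70-fold lower, its second probe set being below the floor on both arrays. With all probe sets of a gene averaged, the signals of Naxd and swa on the array labelled tdf were below the floor. The log2 ratio of Naxd was then bounded at -0.91 or lower in place of -2.74, and the log2 ratio of swa at -1.44 or lower in place of -3.51 or lower.

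The highest ratios belonged to a mixed set of genes. The glutaminyl cyclase gene isoQC had 118 on the yw array and 1815 on the array labelled tdf, 15.4-fold higher. That probe set has a suffix letter in its name. The other probe set of isoQC, a plain one, had 451 and 517, so with plain probe sets only this gene was not 2-fold apart. CG7567 was 7.60-fold higher (290 against 2204), CG13044 6.89-fold higher (635 against 4375), CG9877 5.76-fold higher and CG14419 at least 6.60-fold higher. Arpc1, a subunit of the actin-nucleating Arp2/3 complex, was 5.91-fold higher (195 against 1151), while its other probe set was below the floor on both arrays. Bili, at 37.9 against 655, was at least 6.74-fold higher, and its other probe set was again below the floor on both arrays. With all probe sets averaged, the log2 ratio of isoQC was 2.07 in place of 3.95 and the log2 ratio of Bili at least 1.11 in place of at least 2.75, and Arpc1 was no longer measured. The transferrin family gene Tsf3 was 5.83-fold higher and the cytochrome P450 gene Cyp6a13 5.43-fold higher. The lipid droplet perilipin Lsd-2 was 3.56-fold higher (200 against 711) and the CDP-diacylglycerol synthase Cds 3.53-fold higher (338 against 1191). The remaining named genes were blanks (at least 4.99-fold higher), RNaseX25 (3.98-fold) and Rbm13 (at least 3.37-fold).

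**Figure D1:**
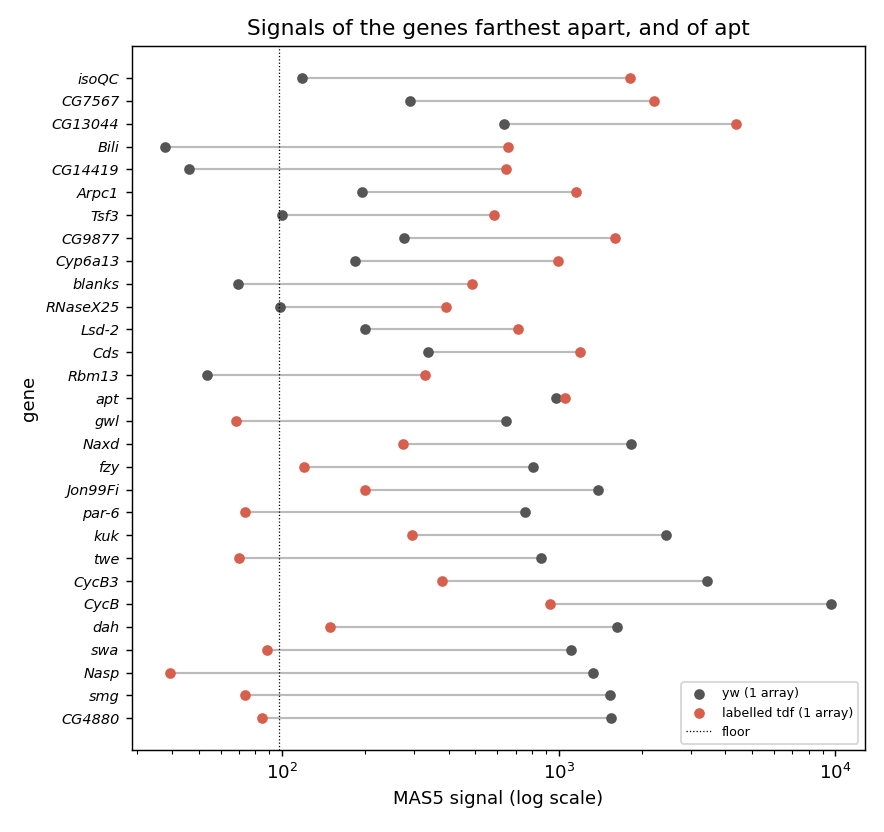
MAS5 signal (log scale) on the yw array (grey) and on the array labelled tdf (red) for the 14 named genes at each end of the ranking and apt, 1 array each, with the floor of 97.3 as a dotted line. CycB lies at 9664 and 928, isoQC at 118 and 1815, and the apt points, 979 and 1051, nearly coincide.

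In all, 275 genes (3.60% of those measured) were at least 2-fold higher and 473 (6.19%) at least 2-fold lower, of which 66 and 108 are lower bounds. At least 4-fold apart were 18 higher and 64 lower genes. The counts and their asymmetry depend on the floor, with 607 higher and 683 lower genes at the 25th percentile and 119 and 267 at the 60th, so that lower genes made up 52.9% and 69.2% of those apart, against 63.2%. Probe sets of the same gene, for 278 genes with 2 or more above the floor on both arrays, had log2 ratios with an SD of 0.533 within a gene, against an SD of 0.594 over all genes above the floor on both arrays. In the simulation with that SD, 193 of 7205 unchanged genes came out at least 2-fold higher and 194 at least 2-fold lower, so many single 2-fold differences are within the spread of the arrays. The simulation used the same SD for dim and bright probe sets, so it may understate such differences among dim genes. Of 26 further probe sets of the genes at least 2-fold apart, 15 had the same direction and 1 was itself at least 2-fold apart that way.

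**Figure D2:**
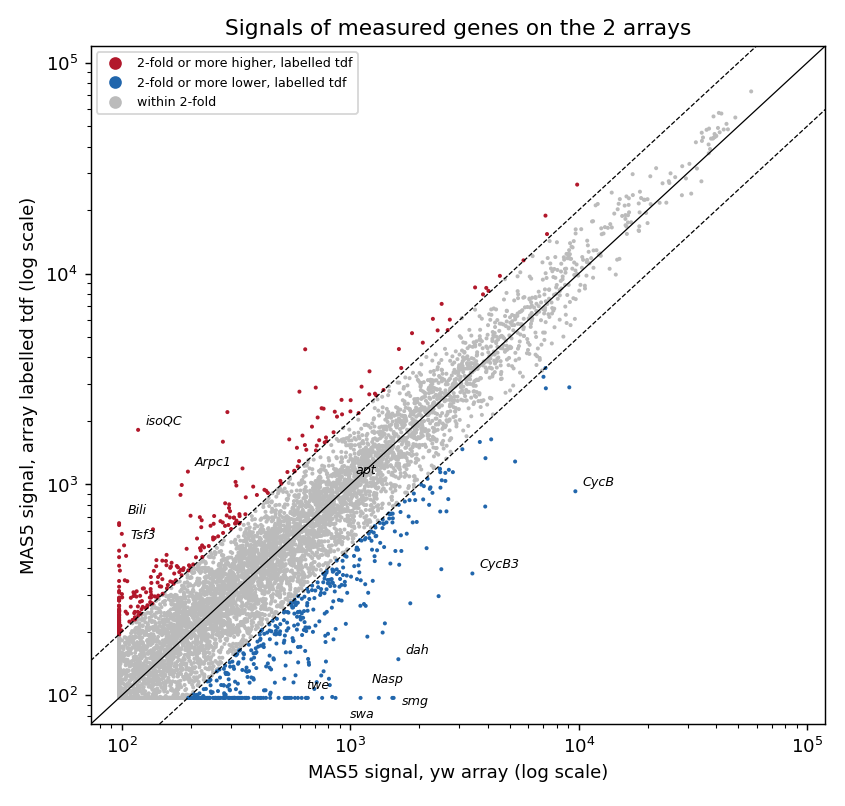
MAS5 signal of the 7639 measured genes on the yw array (x axis) and on the array labelled tdf (y axis), both log scales, 1 point per gene, with signals below the floor of 97.3 drawn at the floor. The solid line marks equal signals and the dashed lines 2-fold; 275 genes (red) lie at or above the upper and 473 (blue) at or below the lower dashed line.

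Cell cycle genes were lower as a group. Of 23 measured, 9 were at least 2-fold lower and none was at least 2-fold higher, and the median log2 ratio of -0.61 was at the 0.01 percentile of matched random lists. Apart from CycB, CycB3, twe and fzy, the lower members were aurB, dup, CycD, Dp and Mcm6, named here after their values were seen. Of 15 germ line genes on the array only 7 were measured. Of these, 3 were at least 2-fold lower, namely CycB, the gap junction gene zpg (473 against 202) and the piRNA pathway gene mael (407 against 202). The median log2 ratio of germ line genes, -0.81, was also at the 0.01 percentile, and was -0.59 without CycB, which both lists hold. The maternal transcript bcd, from the list of early segmentation genes, moved with these groups, at 330 against 54.1 (at least 3.39-fold lower), while that list as a whole had a median of 0.29 (88th percentile, but 0.07 with a floor at the 60th percentile), with 1 of its 14 measured genes lower and none higher. Among the poly(A) controls spiked into the RNA, the 6 above the floor on both arrays had a median log2 ratio of -0.91. Whether this bears on the ratios of fly genes was not tested. The ratio of 3' to 5' signal, a sign of RNA quality, was higher for actin (32.7 on the yw array and 52.3 on the array labelled tdf), eIF-4a (45.5 and 56.6) and 18S rRNA (14.9 and 32.2) but not for GAPDH (22.8 and 17.3).

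Of 8 measured JAK/STAT pathway genes, 3 were at least 2-fold lower and 1 higher. The PIAS homologue Su(var)2-10 was at least 4.14-fold lower (403 against 80.4), the phosphatase Ptp61F 3.14-fold lower (892 against 284) and the receptor dome 2.76-fold lower (1008 against 366), whereas the transcription factor gene chinmo was 2.18-fold higher (251 against 549). The median of -0.70 was at the 0.21 percentile. It was -0.26 when all probe sets of a gene were averaged (9.07 percentile, inside the 2.5 to 97.5 percentile range), where Ptp61F turned to a log2 ratio of at least 0.27. Over the 6 members above the floor on both arrays the median was -0.26 (11.8 percentile). That filter drops Su(var)2-10 and Socs44A (158 against 64.5) for being below the floor on the array labelled tdf. It therefore raises the median by construction and cannot show that the list lies inside the range.

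Cuticle protein genes were higher as a group, by a small amount. The median log2 ratio of the 79 measured was 0.36, above the medians of all 10000 random lists, and 59 had a ratio above 0. At least 2-fold higher were 8, among them TwdlD (9840 against 26409, 2.68-fold), Cpr49Af (2.63-fold) and Cpr78Cb (2.57-fold). Lower by that size were 2, Cpr72Ea (at least 3.03-fold) and Cpr49Ac (at least 2.33-fold), the latter named after its values were seen. The brightest member, TwdlM, had 41034 and 57775, a log2 ratio of 0.49.

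Midgut genes, chiefly digestive enzymes, were split. Of 40 measured, 7 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.29 (99.87 percentile). The lower genes were the serine proteases Jon99Fi (1385 against 199), Jon25Biii (746 against 124), Jon99Fii (591 against 143) and epsilonTry (916 against 282). Jon99Fii was read by a probe set marked as shared within a gene family, so its signal cannot be assigned to this gene alone. Among the higher genes, named after their values were seen, were the maltases Mal-A4 (3.03-fold), Mal-B1 (2.96-fold) and Mal-A2 (2.68-fold) and the proteases yip7 (2.77-fold) and zetaTry (2.56-fold).

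Tracheal and heart genes, tissues in which apt is known to act, had medians inside the 2.5 to 97.5 percentile range of random lists. The trachea list had a median of 0.26 (96.4 percentile), with 2 of 24 measured genes at least 2-fold higher, Osi18 (147 against 375) and the signalling antagonist sty (278 against 589), and none lower. The heart list had a median of 0.31 (97.465 percentile, but a median of 0.06 with a floor at the 25th percentile), with 1 of 13 higher, the LIM homeobox gene tup (192 against 496), and none lower. The Hedgehog pathway list had a median of 0.28 (93.25 percentile), with 1 of 10 higher, rdx (875 against 2097), an adaptor for degradation of Cubitus interruptus, and none lower.

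Of the other lists of differentiated tissues, muscle structure had a median of 0.20 (90.7 percentile, 29 measured, but 0.04 under quantile normalisation), neurons 0.19 (88.5 percentile, 23 measured), hemocytes 0.04 (37.8 percentile, 23 measured) and the salivary gland 0.00 (34.3 percentile, 8 measured), and none of their genes was at least 2-fold apart. The Osiris family had a median of 0.19 (76.1 percentile, but 0.05 under loess) with Osi18 as the 1 higher gene of 17. Glia had 0.00 (50.9 percentile), with moody higher (2.02-fold, but under 2-fold with centring, quantile normalisation or loess) and Ama lower (2.14-fold) among 13. The fat body had -0.01 (34.0 percentile), with Lsd-2 higher and Gnmt lower (2.38-fold) among 18. Malpighian tubule genes had 0.03 (41.3 percentile), with ct higher (at least 2.24-fold) among 14. The signs of the glia, fat body, salivary gland and Malpighian tubule medians, all near 0, changed with the scaling, the floor or the probe sets used. Chitin, tanning and barrier genes had 0.05 (52.4 percentile) with none of 36 apart.

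Among the remaining lists, detoxification genes went both ways, with 11 of 99 higher and 5 lower (median 0.08, 73.4 percentile). Cyp12e1 was 3.29-fold higher and Cyp4p2 4.18-fold lower. The initiator caspase Dronc was the 1 lower gene of 14 in the cell death list (661 against 210, median -0.08, 23.8 percentile). In the heat shock list Hsp26 was the 1 lower gene of 8 (2514 against 1047, median -0.08, 24.5 percentile), and in the immune list Drsl5 the 1 higher gene of 9 (222 against 487, median 0.15, 76.2 percentile, turning to -0.02 under loess). None was 2-fold apart among 21 ecdysone genes (0.06, 56.3 percentile), 10 glycolysis genes (0.15, 67.0 percentile), 12 homeotic and head patterning genes (0.15, 81.3 percentile), 10 eggshell and yolk genes (0.28, 93.8 percentile, but 0.10 under loess and 0.51 over members above the floor on both arrays), 6 dosage compensation and sex genes (0.17, 65.7 percentile, turning to -0.25 with a floor at the 25th percentile), 33 ribosomal protein genes (0.18, 66.1 percentile, turning to -0.03 under quantile normalisation) or 7 housekeeping genes (-0.15, 7.31 percentile), where the values in parentheses are the median and its percentile. Of the 29 lists, 5 had a median outside the 2.5 to 97.5 percentile range. For lists of random genes this range leaves 1.45 outside by construction. Genes of a list may move together and lists share genes, such as CycB, so the comparison does not measure an excess. Of these 5 lists, all but the JAK/STAT list stayed outside the range under every scaling, floor and choice of probe sets tried. Of the 50 measured genes among the 50 neighbours of apt on each side, 10% were at least 2-fold apart, against 9.79% of genes elsewhere, and of the 245 among the 250 on each side 6.53%, against 9.90%, differences that were not tested.

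**Figure D3:**
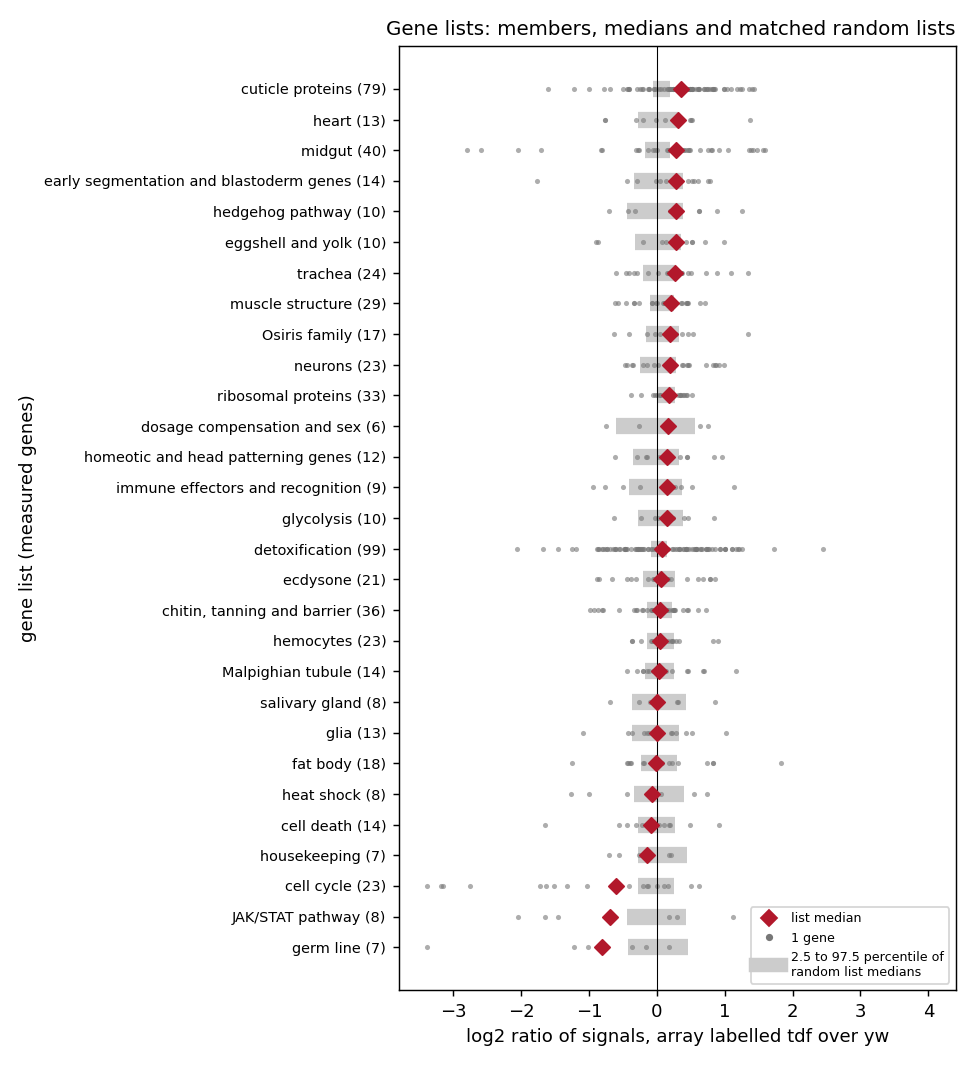
Log2 ratio of signals (array labelled tdf over yw) for the measured genes of each of the 29 lists (grey points), with the list median (red diamond) and the 2.5 to 97.5 percentile range of medians of matched random lists (grey bar). The medians of the cell cycle (-0.61), germ line (-0.81) and JAK/STAT (-0.70) lists lie left of their bars and those of the cuticle (0.36) and midgut (0.29) lists right of theirs.

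Controls differed between the arrays by kind. The 9 hybridisation controls, added after labelling, had a median log2 ratio of -0.07 with an SD of 0.15. Of the 12 poly(A) controls, which are spiked into the RNA before labelling, 11 were lower, and the 6 above the floor on both arrays had a median of -0.91 with an SD of 0.11. The ratio of 3' to 5' signal, which is larger in more degraded or less completely copied RNA, was higher on the array labelled tdf for actin, eIF-4a and 18S rRNA and lower for GAPDH. On both arrays the 3' signal was many times the 5' signal for each of these transcripts. The ratios ran from 14.9 (18S rRNA, yw array) to 56.6 (eIF-4a, array labelled tdf), so this limit holds for both RNAs and for every gene ratio given here.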

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

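The test of the yeast controls was chosen after the result was seen. Yeast control probe sets, which have no target in fly RNA, were not used in any comparison, and 3 of the 4 were above the floor of 97.3 on the array labelled tdf and below it on the yw array. WBP1 had 54.5 on the yw array and 195 on the array labelled tdf, URA3 59.1 and 157, and RIP1 64.2 and 223, and the median log2 ratio of all 4 was 1.82. A higher unspecific background on that array is a candidate explanation, and it was tested on the 7 mouse and tryptophan control probe sets, which should be dark as well. Their median log2 ratio was 0.64, with 5 higher and 2 lower. All 7 were below the floor on both arrays, where ratios are noisy, so they cannot decide the question. A biological source of a yeast signal was not tested, and bounds that rest on signals near the floor carry this uncertainty.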

How the results depend on the processing

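The counts over genes with a mean signal of at least 500, the medians over members above the floor on both arrays and the germ line median without CycB were chosen after the data were examined. Under centring, quantile normalisation and loess, 254 to 288 genes were at least 2-fold higher and 440 to 499 lower, and the medians of the cell cycle, germ line, JAK/STAT, cuticle and midgut lists kept their sign. The apt log2 ratio stayed between 0.08 and 0.18. Of 1049 values for the log2 ratios of 155 named genes, 997 moved by less than the spread between probe sets of a gene, 51 moved by more, and 1 reversed: Ptp61F was at 0.27 or higher with the mean of all probe sets, because its other probe set, below the floor on both arrays, had 2.42 and 48.7 and was averaged without the floor.

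A floor at the 25th percentile gave 607 higher and 683 lower genes, so that 52.9% of the genes apart were lower, against 63.2% with the main floor, with a JAK/STAT median of -0.99 and 5 lower germ line genes. A floor at the 60th percentile, which measures fewer genes, gave 119 higher and 267 lower genes, 4 higher and 0 lower cuticle genes, 4 higher midgut genes and 1 lower germ line gene. The mean of all probe sets gave a JAK/STAT median of -0.26 (9.07 percentile) with 0 higher members, and plain probe sets gave a midgut median of 0.39. A limit of 1.5-fold, which admits more genes by construction, gave 1005 higher and 1171 lower genes, 1 higher cell cycle gene, 25 higher and 5 lower cuticle genes, 12 higher midgut genes and 5 lower JAK/STAT genes. At 3-fold there were 35 higher and 136 lower genes, 0 higher and 1 lower cuticle gene, 1 higher midgut gene, 0 higher JAK/STAT genes and 1 lower germ line gene. At 3 local median absolute deviations there were 41 higher and 111 lower genes, 4 lower cell cycle genes, 1 higher and 0 lower cuticle genes, 1 higher midgut gene, 0 higher and 1 lower JAK/STAT gene and 1 lower germ line gene. Members above the floor on both arrays gave a JAK/STAT median of -0.26, which that filter raises by construction. A mean signal of at least 500 left 82 higher and 164 lower genes. Except where stated, the cause was not tested.

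Of 230 medians of the 29 lists, 16 moved by more than the spread of random lists. Under quantile normalisation the median log2 ratio of Osiris family genes was 0.0047, the median log2 ratio of muscle structure genes 0.043 and the median log2 ratio of ribosomal proteins -0.030. Under loess these were 0.045, 0.035 and -0.082, and the median log2 ratio of eggshell and yolk genes was 0.10. A floor at the 25th percentile put the median log2 ratio of heart genes at 0.057 and the median log2 ratio of dosage compensation and sex genes at -0.25, a floor at the 60th percentile put the median log2 ratio of early segmentation and blastoderm genes at 0.068, the mean of all probe sets put the median log2 ratio of glia genes at 0.21, and members above the floor on both arrays put eggshell and yolk at 0.51. At the 60th percentile floor the salivary gland, eggshell and yolk, and dosage compensation and sex lists had too few measured genes for a median. Of 574 counts of list members at each size, 450 stayed within 1.5 times the main count and 124 did not. Among the lists inside the random range, scaling alone changed small counts, to 0 higher glia genes under all 3 scalings, 1 lower chitin, tanning and barrier gene and 2 lower heat shock genes under centring, 1 higher neuron gene under quantile normalisation and loess, 1 higher homeotic or head patterning gene under quantile normalisation and 1 lower immune gene under loess. Signal over background limits dim genes, whose ratios rest on the floor. Of 26 further probe sets of genes at least 2-fold apart, 15 went the same way, 1 of them by at least 2-fold. Across 278 pairs of probe sets of 1 gene, not independent replicates, the log2 ratios had a Pearson r of 0.15 (Spearman rho 0.18). It was 0.47 (rho 0.55) among the 52 pairs with the dimmer probe set at 512 or more.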

Other observations

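Lists of maternal transcripts and of DNA replication genes were written after the genes with the lowest ratios had been seen, from genes whose own values had not been looked at, and the tests of cell division, of blastoderm RNA and of the cuticle genes were chosen after the results were seen. Of 42 maternal transcripts on the array, which the mother loads into the egg, 28 were measured and the rest were below the floor on both arrays. Among the 28, tor, wisp, plu and fs(1)N were above the floor on the yw array alone, so their ratios are lower by construction. Of the 28 measured, 8 were at least 2-fold lower on the array labelled tdf and none was higher. The median log2 ratio of the 28, -0.53, was below the medians of all 10000 matched random lists. Among the 8 lower were the translational repressors pum (686 against 200) and brat (1533 against 727), the receptor genes tor (279 against 27.2) and Tl (894 against 385), and me31B (1897 against 906). Of the 28, 4 had a ratio above 0, the highest vls (231 against 405), and alphaTub67C was nearly equal (175 against 173). The brightest of the list, mod, had 9614 and 6096. The 25 added DNA replication genes had a median of 0.07 (64.3 percentile), with 3 lower and 1 higher, and together with the replication genes of the cell cycle list, 34 in all, a median of -0.08 (21.1 percentile), with 5 lower and 1 higher. The histone-binding Caf1-55 had 2685 and 852.

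Cyclin E and hedgehog, singled out after their values were seen as genes linked to apt elsewhere, gave little to compare. CycE had 248 on the yw array and 170 on the array labelled tdf, a log2 ratio of -0.55, which is about the spread between probe sets of a gene. The signal of hh was below the floor on both arrays (32.5 and 54.9).

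The low maternal and cell cycle transcripts may come from RNA of eggs or of the first hours of development in the yw collection. This predicts a median of -0.5 or lower for maternal transcripts outside the first lists. It was -0.53, past that limit by less than the SD of random lists (0.11). None of the 28 genes was shared with those lists, although how many of them late embryos or dividing cells also express was not counted. The result therefore does not tell this source from fewer dividing cells. Zygotic RNA of blastoderm-stage embryos stays open as a source. The 12 early segmentation and blastoderm genes without the maternal bcd and cad had a median of 0.39 (96.3 percentile). Only 2 of them were above the 60th percentile floor on the yw array, so they cannot decide it. The genes dah (10.9-fold) and kuk (8.24-fold), which act in cellularisation, were lower, but whether their RNA is maternal or zygotic was not tested. The scaling of the arrays is argued against by 440 lower and 288 higher genes under quantile normalisation and 480 lower and 254 higher under loess. Fewer dividing cells in the mutant stay open, because the median of the 24 maternal transcripts that are not cell cycle regulators (-0.53) lay below that of all replication genes by a difference of -0.45 but not beyond the set limit of -0.5 by more than the spread of random lists, and dividing cells may express some of them. With 1 collection and 1 array per genotype, an effect of tdf and a difference in staging or egg content also stay open. The yw stock and the tdf line may also differ elsewhere in the genome, and tdf homozygotes were picked by GFP. Neither can be told apart from an effect of tdf here. RNA quality stays open too and was not tested. The 3' to 5' ratio was 32.7 on the yw array and 52.3 on the array labelled tdf for actin, 45.5 and 56.6 for eIF-4a and 14.9 and 32.2 for 18S rRNA, but 22.8 and 17.3 for GAPDH.

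The higher cuticle protein signals may in part reflect a single factor for all late genes, as dilution of the yw RNA by early RNA would give. The other 12 lists of differentiated tissues together (241 genes) had a median of 0.15 (99.7 percentile). This median was 0.13 (99.7 percentile) under centring. Under quantile normalisation it was 0.085 (92.9 percentile) and under loess 0.071 (96.1 percentile), both inside the percentile range set for the lists. A rise of these genes beyond random lists therefore depended on the scaling. The main median of 0.15 was lower than the cuticle median by 0.21, more than the 0.15 that is 2 SD of such differences between random lists. Genes of a list may move together, so this gap cannot decide against a single factor for all genes of these lists as the whole cause. The same limit holds for the differences list by list below. Dilution is not decided either, because some of these genes, such as the maternal cad in the Malpighian tubule list, may be in early RNA too, and how many was not counted. The difference was 0.26 under quantile normalisation and 0.24 under loess, again above 2 SD. List by list it was above 2 SD for chitin, tanning and barrier genes (0.34), hemocytes (0.32), fat body (0.37) and Malpighian tubule (0.33), and not for the other 8 lists, with trachea (0.08), heart (0.05) and midgut (0.07) the closest, nor for muscle structure, neuron and Osiris genes together (69 genes, median 0.20, difference 0.16 against 2 SD of 0.18), so these could share a factor with the cuticle genes. A later mean stage of the embryos on the array labelled tdf, other differences between the stocks and an effect of tdf on cuticle genes stay open and were not tested.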
